A study of Homo sapiens with 12 samples.

How the data were processed

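The series holds snRNA and snATAC libraries made from nuclei of human liver with a multiome assay. The 12 samples used here are 6 libraries per assay, from 2 control and 4 Fontan livers, with 1 library per donor and assay. Groups and replicate numbers follow the labels, which name controls 1 and 3 and Fontan 1 to 4 and give no batch, day or sequencing run. The control tissue came from operations for a liver tumour, so group and reason for surgery cannot be separated.

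The deposited snRNA matrices hold raw counts per feature and barcode, which are UMIs for genes and counts for peaks, made with cellranger-arc 1.0.1 per the file headers. Cell Ranger 2.0.0 and the genome build hg38 are named per the submitters' processing notes, and this difference in version was not resolved. The deposited snATAC matrices also hold raw counts, per peak and barcode, and their peak lists differ between libraries. Whether reads in introns were counted is not stated. Nothing was normalized in these files.

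Nuclei were kept with at least 500 UMIs, at least 300 genes and at most 10% mitochondrial UMIs. Doublets were scored per library with scrublet in scanpy 1.11.5 (Python 3.11.15) and removed above a score of 0.25, because the automatic threshold called 2 nuclei in all. Nuclei were clustered with 2000 variable genes, 30 principal components, 15 neighbours and the Leiden method (leidenalg 0.10.2, igraph 0.11.9) at a resolution of 1, in 2 rounds that split hepatocyte-like from other nuclei. Variable genes were ranked by library, and each gene was centred within each library before the components were computed. No other correction between libraries was made. A cluster took a class name, written with "-like", from marker lists fixed before the data were examined. It needed at least 3 detected markers, a marker score of at least 1.5 (log2), a margin of 1 over the next class and a marker among its 10 leading genes. Clusters mixed with hepatocyte RNA stayed unnamed. The doublet score, the naming thresholds and the 2 rounds were set after the data were examined.

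Total UMIs per library in the deposited barcodes ranged from 12473165 to 64315913, and after the filter from 9350485 to 47651333. Total counts per snATAC library ranged from 2637888 to 56385080. Shares of nuclei in single libraries are given with Wilson 95% intervals, which cover counting error only, and a share of 0 with the limit that 3 counts give.

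UMI counts were summed per library and class, so the library is the replicate. A class was tested where each group kept 2 libraries with at least 20 nuclei. Genes were compared with edgeR 4.0.16 (R 4.3.3), with TMM factors, its expression filter by group and robust quasi-likelihood F tests, and p-values were adjusted by the Benjamini-Hochberg method to a threshold of 0.05. CPM were computed on library sizes scaled by these factors, and the SE of a log2 fold change is its size divided by the square root of F. Gene lists written before the data were examined were tested with fry in limma 3.58.1, adjusted over 54 pairs of a list and a class, and single members were also adjusted over the list alone. Of the 54 pairs, 32 are described with their tests, a choice made after the data were examined. Shares and quality values were compared with two-sided exact permutation tests, in which 15 regroupings give no p under 0.133.

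For zonation, hepatocyte-like nuclei were thinned to 1000 UMIs and ranked by pericentral against periportal transcripts, and the change of the zone difference with the group was tested in edgeR with the library as a block. Peaks were merged into 323850 regions, of which 50239 had a peak in every library, and autosomal ones among these were tested with edgeR after its filter. Each gene start was joined to regions within 1000 bases. Correlations were computed in R and NumPy, permutation tests and Wilson intervals with SciPy 1.17.1, and figures were drawn with matplotlib 3.10.9.

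Named genes follow a rule set before the data were examined. It names the passing genes with the largest change whose groups do not overlap, 10 and 10 in hepatocyte-like nuclei and 5 and 5 in other classes. It adds up to 4 members with the smallest p in each described list, and a set of genes allowed whatever their result. Some genes that the rule names are not reported here. MT-ATP8 in macrophage-like nuclei, SLC40A1, GLYAT and ESR1 in hepatocyte-like nuclei and ZNF248, PAM, BCAT1 and SEMA4C in endothelial-like nuclei lie outside it and were chosen after their values were seen.

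Alternatives were DESeq2 1.42.0, its size factors in edgeR, no low-count filter, at least 1000 or 300 UMIs per nucleus, doublets kept, the replicate number as a block, camera in place of fry, other zone and region definitions, and leaving out each library in turn. A mitochondrial limit of 25%, wider classes, thinning to 500 UMIs or none, and regions covered by peaks to 80% were added after the data were examined. The replicate block leaves few residual degrees of freedom, and it gave an adjusted fry p of 0.995 for all 54 pairs of a list and a class. An upper end of 0.995 in the range of a list mostly comes from this block and says little about how firm the list is. Lower ends are not all fry values, and several come from camera with a preset correlation of 0.01 in all libraries. In hepatocyte-like nuclei these are the drug metabolism, pericentral, fatty acid, coagulation, acute phase, immediate early, hypoxia, stress-response and mitochondrial lists. In stellate-like nuclei they are the fibrillar matrix and quiescent lists. Where a control library is left out, the lone control is assumed to vary like the Fontan group. Fontan replicate 3 stood out in these same data by lying with the controls. Leaving it out therefore widens the group difference by selection. Passes and p-values without it are descriptive and are not tests of a group effect.

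The edgeR tests of classes, zones and regions were tested on simulated data with 200 genes or regions changed by a known fold. At 16-fold, 72.7% of changed genes were recovered among 21437 genes simulated for hepatocyte-like nuclei, 73.4% of 4593 for stellate-like, 73.8% of 11315 for endothelial-like and 95.3% of 6347 for macrophage-like nuclei. At 4-fold these shares were 3.17%, 10.9%, 17.5% and 54.0%, and at 2-fold 0%, 0%, 0% and 6.25%. For the zone test they were 86.4%, 69.7% and 13.8% at 16-fold, 4-fold and 2-fold (17323 genes), and for regions 98.5%, 68.7% and 26.9% (44987 regions). Of the calls made on simulated data, 10.7% were wrong for hepatocyte-like nuclei, 6.90% for stellate-like, 0% for endothelial-like, 2.94% for macrophage-like, 6.67% for zones and 9.79% for regions. T/NK-like and cholangiocyte-like nuclei were too few to test, and sex chromosomes were left out of the region test.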

Results

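Nuclei from frozen human liver were profiled with a droplet assay that reads gene expression (snRNA) and accessible chromatin (snATAC) from the same nucleus. The livers came from people with a Fontan circulation, in which venous blood reaches the lungs without passing through a pumping ventricle, and from controls without it, whose tissue came from operations for a liver tumour. The comparison asks how the cells of the Fontan liver differ from those of the control liver, cell type by cell type. Each assay had 2 control libraries, replicates 1 and 3, and 4 Fontan libraries, replicates 1 to 4, which makes 12 samples. The deposited snRNA files held 10686 and 19506 barcodes in the controls and between 6359 and 12360 in the Fontan libraries. After the filter on UMIs, genes and mitochondrial RNA, 5970 and 8938 control nuclei and 6458, 5070, 9135 and 4565 Fontan nuclei remained. Control nuclei were shallower, with medians of 1221 and 2480 UMIs against 3561, 7707, 2081 and 3915 in the Fontan libraries (two-sided exact permutation p = 0.267). Total UMIs per library after the filter ranged from 9350485 to 47651333.

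Endothelial-like nuclei, which line the sinusoids and vessels, made up 13.3% ± 4.86 of Fontan nuclei (SD, n = 4) and 1.87% ± 0.725 of control nuclei (SD, n = 2). The lowest Fontan library, at 7.83% (Wilson 95% CI 7.29 to 8.40), lay above the highest control, at 2.38% (2.02 to 2.80). T/NK-like lymphocytes made up 2.16% ± 0.430 of Fontan nuclei and 0.182% ± 0.0986 of control nuclei, again with no overlap. Hepatocyte-like nuclei made up 66.2% ± 5.85 of Fontan nuclei and 84.6% ± 0.0781 of control nuclei. Each of these 3 differences had a two-sided exact permutation p of 0.133, the smallest that the 15 regroupings of 2 and 4 libraries can give, so the design cannot reach 0.05. Cholangiocyte-like nuclei, of the bile ducts, were 2.49% ± 2.15 against 0.604% ± 0.617 (exact p = 0.267), and 1 Fontan library lay below the higher control. Macrophage-like nuclei were 4.77% ± 3.24 against 3.53% ± 1.66 (exact p = 0.933) and stellate-like nuclei 1.51% ± 0.930 against 1.04% ± 0.408 (exact p = 0.667). The macrophage difference of 1.23 percentage points turned to −0.376 when Fontan replicate 3 was left out, and was 1.93 without Fontan replicate 2, 2.40 without control replicate 1 and 0.0588 without control replicate 3. The stellate difference of 0.471 was 0.0747 without Fontan replicate 3, 0.793 without Fontan replicate 4, 0.183 without control replicate 1 and 0.760 without control replicate 3. Leaving out Fontan replicate 4 moved the cholangiocyte difference from 1.88 to 0.828. A mitochondrial limit of 25% moved it to 3.39, with 10.7% in Fontan replicate 4. Smooth-muscle-like nuclei numbered 2, 8, 0 and 16 in Fontan replicates 1 to 4 and 0 in both controls, or 0.135% ± 0.159 against 0% (exact p = 0.4), and 0.0629% without Fontan replicate 4.

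**Figure D1:**
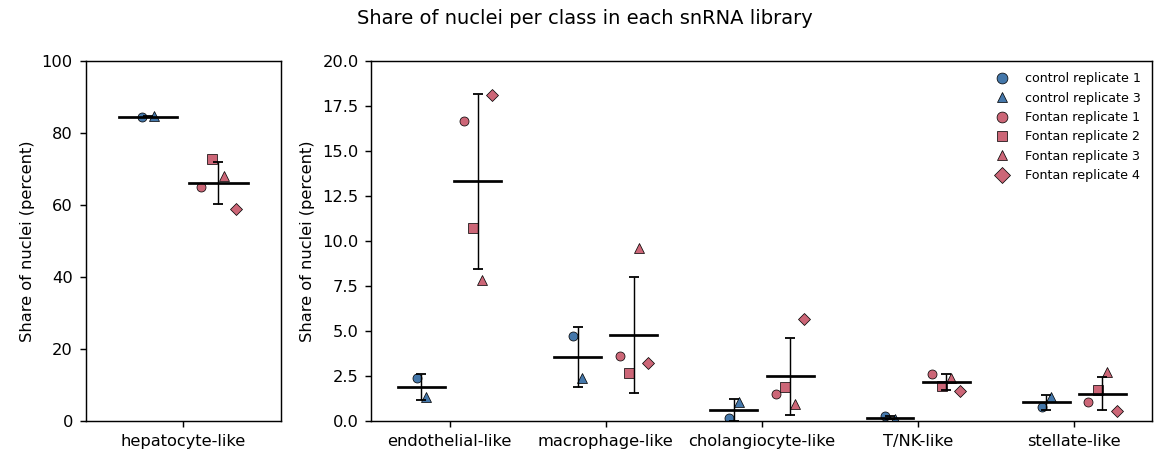
Share of nuclei in percent (y axis) for each cell class (x axis) in the 2 control libraries (blue) and 4 Fontan libraries (red). Points are libraries, horizontal bars are group means and error bars are SD; the Fontan points of the endothelial-like class (mean 13.3%) and the T/NK-like class (mean 2.16%) all lie above the control points (means 1.87% and 0.182%).

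These shares stood beside a gap in depth and in RNA quality. Barcodes over the mitochondrial limit made up 16.1% and 52.9% of the deposited control barcodes and 3.96%, 24.1%, 8.51% and 26.1% of the Fontan barcodes. Clusters left unnamed because their nuclei also held much hepatocyte RNA were 7.27% ± 1.38 of control nuclei and 4.37% ± 1.22 of Fontan nuclei. Unnamed clusters with no marker among the leading genes were 0.257% ± 0.0155 and 2.11% ± 1.13, those with too low a marker score 0% and 2.35% ± 2.21, and those with 2 classes scoring close 0.648% ± 0.0167 and 0.556% ± 0.820. Part of these clusters, among them the mixed ones, was then counted in the best class, which left 0.780% ± 0.0108 of control nuclei and 3.20% ± 1.70 of Fontan nuclei unnamed. With these wider classes endothelial-like nuclei were 4.72% ± 0.0182 of control nuclei and 14.8% ± 4.16 of Fontan nuclei (exact p = 0.133). The T/NK-like difference was then 0.696 percentage points in place of 1.97 (exact p = 0.667). Stellate-like nuclei were then 2.75% ± 1.26 of Fontan nuclei and 1.05% ± 0.397 of control nuclei, with all Fontan libraries above both controls (exact p = 0.133). With nuclei of 1000 or more UMIs, macrophage-like nuclei were 3.22% ± 1.57 of Fontan nuclei and 1.37% ± 0.616 of control nuclei, also with no overlap (exact p = 0.133). At that minimum endothelial-like nuclei were 10.3% ± 5.06 against 0.325% ± 0.233 and T/NK-like nuclei 1.06% ± 0.671 against 0.0133% ± 0.0189 (exact p = 0.133 for both), so the T/NK-like difference was 1.05 percentage points in place of 1.97.

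In hepatocyte-like nuclei, genes of drug metabolism were higher in most Fontan libraries. CYP2C8, a cytochrome P450 that oxidises many drugs (ENSG00000138115, chromosome 10), stood at 2977 ± 1438 CPM (SD) in the 4 Fontan libraries and 526 ± 38.7 in the 2 controls, a log2 fold change of 2.50 ± 0.66 (SE). CYP1A2, which metabolises caffeine, stood at 72.6 ± 75.2 CPM against 4.85 ± 0.308 (log2 3.90 ± 1.05). CYP2A6, which oxidises nicotine, differed by 2.01 ± 0.72 and CYP4A11, a fatty acid hydroxylase, by 3.21 ± 1.13; both have a closely related copy, so reads can be assigned to the wrong one. CYP3A4 stood at 1269 ± 745 CPM against 1249 ± 324 (log2 0.02 ± 0.66, turning to −0.026 with the size factors of DESeq2), and CYP2E1 differed by 0.16 ± 0.56. CYP3A4 turned to −0.35, −0.17 and −0.32 without Fontan replicate 3, Fontan replicate 4 and control replicate 1, and CYP2E1 to −0.17 and −0.48 without Fontan replicate 1 and control replicate 1. Of the 16 measured members of the drug metabolism list, 15 were higher and 1 lower, with a median log2 fold change of 1.46. Over all genes tested 0 members passed edgeR's quasi-likelihood test (7 at an unadjusted p under 0.05), and adjusted over the list alone CYP2C8 and CYP1A2 passed (adjusted p = 0.0448 for both). The list as a whole had an adjusted p of 0.547 in limma's rotation test fry, over the 54 pairs of a list and a class. When Fontan replicate 3 was left out, 9 members passed over all genes, each higher in Fontan, and the list had an adjusted fry p of 0.0537 (0.00311 to 0.995 over its alternatives). That library was singled out in these same data because it lies with the controls, so results without it, here and below, are descriptive.

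Genes of the pericentral zone, the part of the lobule next to the central vein, went the same way in 13 of 16 members (median log2 1.14, fry, adjusted p = 0.547). RHBG, an ammonium transporter, differed by 4.79 ± 1.38 and ADH1B, an alcohol dehydrogenase, by 2.98 ± 1.08. GLUL, the glutamine synthetase of the innermost pericentral cells, went the other way, at 38.7 ± 14.0 CPM in Fontan and 64.7 ± 21.5 in controls (log2 −0.74 ± 0.41). Of the 16 periportal genes, 12 were higher (median log2 0.34, fry, adjusted p = 0.547), among them GLS2, the liver glutaminase (3.17 ± 0.94), and HSD17B13, a lipid droplet enzyme (3.14 ± 0.96). None of the members of either list passed over all genes in edgeR's test or adjusted over the list alone, with 7 pericentral and 5 periportal members at an unadjusted p under 0.05. With Fontan replicate 3 left out, the median log2 was 1.31 for the pericentral and 0.09 for the periportal list. In that fit 7 pericentral and 5 periportal members passed as higher and 1 and 3 as lower, at adjusted fry p of 0.0768 (0.00697 to 0.995 over its alternatives) and 0.189 (0.189 to 0.995).

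Several genes of glucose and bile acid handling also had higher means in Fontan. G6PC, which releases free glucose from the liver, stood at 655 ± 471 CPM against 102 ± 6.36 (log2 2.68 ± 0.84), and PFKFB1, which sets the balance of glycolysis and gluconeogenesis, differed by 1.84 ± 0.57. PKLR, the liver pyruvate kinase, differed by 2.70 ± 0.93 and GYS2, the liver glycogen synthase, by 1.77 ± 0.63. The glucose list had 11 of 16 members higher and 5 lower (median log2 0.53, fry, adjusted p = 0.195). SLC10A1, the main bile acid uptake carrier of hepatocytes, stood at 130.2 ± 95.4 CPM against 4.28 ± 0.116 (log2 4.93 ± 1.44), with 3.30 CPM in Fontan replicate 3. AKR1D1, a reductase of bile acid synthesis, differed by 4.72 ± 1.36, SLC27A5, a bile acid CoA ligase, by 2.18 ± 0.78, and NR0B2, the nuclear receptor that represses bile acid synthesis, by 2.03 ± 0.68. CYP7A1, the rate-limiting enzyme of bile acid synthesis, was low, at 16.1 ± 24.4 CPM in Fontan and 0.413 ± 0.519 in controls (log2 5.48 ± 2.13). The bile acid list had 11 of 16 measured members higher and 5 lower (median log2 1.30, fry, adjusted p = 0.535). In both lists 0 members passed over all genes in edgeR's test or adjusted over the list alone, with 6 glucose and 8 bile acid members at an unadjusted p under 0.05. Both lists passed fry with Fontan replicate 3 left out (adjusted p = 0.0119 for each, and 0.0119 to 0.995 over the alternatives of each list). With all libraries, camera with an estimated correlation gave each list an adjusted p of 0.811.

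Most fatty acid oxidation genes had higher means in Fontan, although the level of the list in Fontan replicate 3 (−1.17) lay between the controls (−1.66 and −0.26). PDK4, a kinase that spares glucose in fasting, stood at 268 ± 192 CPM in Fontan and 5.31 ± 1.86 in controls (log2 5.65 ± 1.45), with 8.96 CPM in Fontan replicate 3. ACADVL, the first enzyme of long-chain oxidation, went the other way, at 136 ± 55.4 against 319 ± 53.6 (−1.23 ± 0.46). Of 18 fatty acid oxidation genes, 16 were higher (median log2 1.41, fry, adjusted p = 0.598). Among coagulation genes, 13 of 17 were higher (median log2 0.63, fry, adjusted p = 0.547), including KNG1, or kininogen (2.62 ± 0.90), PLG, or plasminogen (1708 ± 708 CPM against 603 ± 142), and SERPIND1, or heparin cofactor (2.28 ± 0.67). In these lists 0 members passed over all genes in edgeR's test or adjusted over the list alone (7 and 4 at an unadjusted p under 0.05), and with Fontan replicate 3 left out 9 fatty acid and 6 coagulation members passed as higher and 1 and 3 as lower. The adjusted fry p of these lists was then 0.156 (0.00311 to 0.995 over its alternatives) and 0.189 (0.0553 to 0.995).

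Acute phase genes, which the liver makes in inflammation, were lower in 3 of the 4 Fontan libraries. ORM1 stood at 156 ± 108 CPM in Fontan and 405 ± 65.1 in controls (log2 −1.38 ± 0.55), with 316 CPM in Fontan replicate 3. Its near-identical neighbour ORM2 differed by −1.06 ± 0.47, so reads can be assigned to the wrong copy. LCN2, an iron-binding acute phase protein, was near the detection limit, at 0.411 ± 0.515 against 4.05 ± 3.65 CPM (log2 −3.31 ± 1.00). Of 18 members 16 were lower (median log2 −1.35, fry, adjusted p = 0.580), 0 passed over all genes in edgeR's test or adjusted over the list alone, and 2 had an unadjusted p under 0.05. When that library was left out, the median was −2.74, with 14 members passing as lower and an adjusted fry p of 0.0119. Over the alternatives the adjusted p ranged from 1.19e-05, given by camera with a preset correlation in all libraries, to 0.995. With all libraries, camera with an estimated correlation (0.658) gave the list an adjusted p of 0.811. Lists of tissue handling and stress had most members lower in this class as well. The immediate early list had 12 of 15 members lower (median log2 −0.68, fry, adjusted p = 0.598) and the hypoxia list 15 of 21 (median log2 −0.22, fry, adjusted p = 0.765). In edgeR 0 of their members passed over all genes or over the list alone, with 1 and 2 at an unadjusted p under 0.05. With the same library left out their medians were −1.57 and −0.996, 7 and 8 members passed as lower and 1 in each as higher, and the adjusted fry p was 0.156 (0.0553 to 0.995 over its alternatives) and 0.189 (0.156 to 0.995). The levels of the immediate early list were −0.23, −1.07, 0.80 and −0.53 in Fontan replicates 1 to 4 and 0.90 and 0.13 in the controls, so the acute phase difference was not separated from handling of the tissue.

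**Figure D2:**
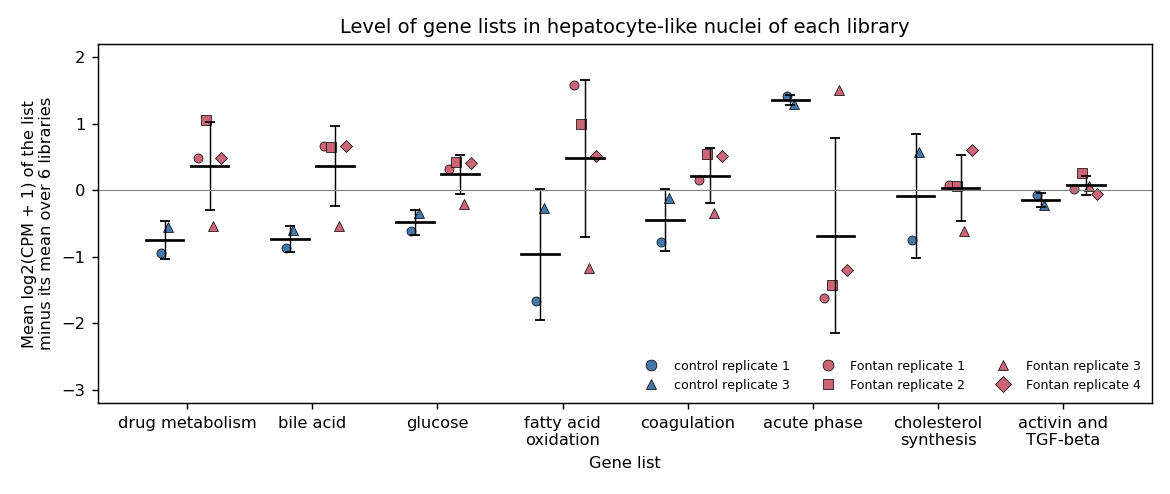
Level of 8 gene lists (x axis) in the hepatocyte-like nuclei of each library, as the mean log2(CPM + 1) of the list minus its mean over the 6 libraries (y axis). Points are libraries, horizontal bars are means and error bars are SD of the 2 control (blue) and 4 Fontan (red) libraries; in the bile acid list Fontan replicates 1, 2 and 4 lie at 0.66 to 0.67 and Fontan replicate 3 at −0.53, near the controls at −0.87 and −0.59.

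Cholesterol synthesis genes showed no shared direction. SQLE, the squalene epoxidase, stood at 27.6 ± 18.0 CPM in Fontan and 30.6 ± 28.5 in controls (log2 −0.15 ± 0.79). HMGCS1 differed by 0.03 ± 0.69 (−0.04 with the size factors of DESeq2), while MVD, which makes isopentenyl diphosphate, differed by −1.34 ± 0.49. The list split into 12 higher and 12 lower members (median log2 0.01, fry, adjusted p = 0.901), of which 0 passed over all genes or over the list alone and 1 had an unadjusted p under 0.05. Without Fontan replicate 3, MVD passed as lower and SQLE turned to 0.10, and SQLE was 1.53 without control replicate 3. HMGCS1 turned to −0.45 without Fontan replicate 4 and to −0.75 without control replicate 1. Activin genes were examined because activins are signals between liver cells. INHBA stood at 69.1 ± 7.13 CPM against 48.1 ± 8.71 (log2 0.52 ± 0.33), INHBB differed by 0.83 ± 0.76 and INHBE by 0.82 ± 0.66, none of which passed with or without Fontan replicate 3. CCN2, a matrix-associated target of TGF-beta, was at 3.39 ± 2.21 CPM against 0.285 ± 0.0102 (3.55 ± 1.07), and ACVR1C, an activin receptor, differed by 1.67 ± 0.52. The activin and TGF-beta list had 18 of 27 members higher (median log2 0.44, fry, adjusted p = 0.547), with 0 passing over all genes or over the list alone and 5 at an unadjusted p under 0.05. Its adjusted fry p was 0.189 without Fontan replicate 3 (0.189 to 0.995 over its alternatives).

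Over all 22270 genes tested in hepatocyte-like nuclei, 0 passed edgeR's quasi-likelihood test at an adjusted p of 0.05, and 2210 had an unadjusted p under 0.05. DESeq2 called 445 of the 15138 genes for which it gave an adjusted p, 433 higher in Fontan and 12 lower. The lowest adjusted p in edgeR was 0.480. Leaving out Fontan replicate 3 gave 4310 calls, 2478 higher and 1832 lower, and leaving out any other library gave 0. Groups did not overlap in 14.8% of genes, where chance gives 13.3%. Control nuclei fell mainly in clusters h0 and h1 and Fontan nuclei in h2 (replicate 1), h6 and h8 (replicate 2), h3 and h4 (replicate 3) and h5 (replicate 4). Clusters of this class thus coincide with the group and, among Fontan nuclei, with the single library. Markers of other liver cells in hepatocyte-like nuclei had 6 members higher and 10 lower (fry, adjusted p = 0.598). Tumour-associated fetal genes had 7 higher and 6 lower (fry, adjusted p = 0.893).

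The libraries did not sort by group. Across genes, the log2 CPM of hepatocyte-like nuclei in Fontan replicate 3 had Pearson correlations of 0.978 and 0.959 with the controls and of 0.869 to 0.889 with the other Fontan libraries, which had 0.967 to 0.974 among themselves. Genes are not independent replicates, so these correlations describe libraries. In stellate-like nuclei Fontan replicate 3 correlated at 0.826 and 0.840 with the controls and at 0.345 to 0.375 with the other Fontan libraries, and in macrophage-like nuclei at 0.911 and 0.858 against 0.747 to 0.771. The endothelial-like gap was small, at 0.798 and 0.779 against 0.775 to 0.791. Its median depth, 2081 UMIs, was also the lowest of the Fontan libraries.

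**Figure D3:**
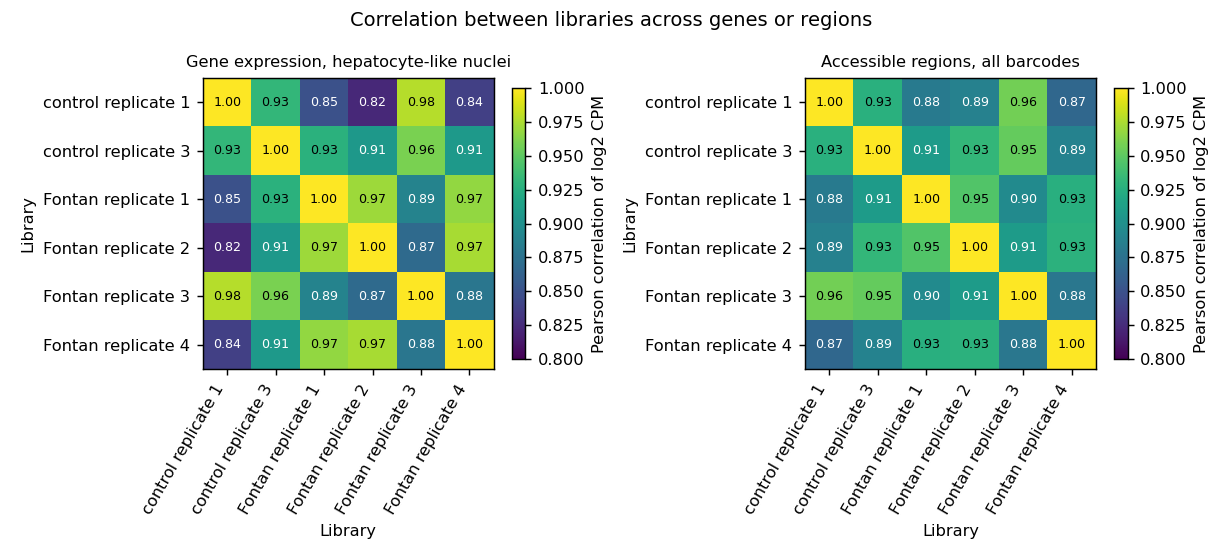
Pearson correlation of log2 CPM between the 6 libraries (both axes), across genes of hepatocyte-like nuclei (left) and across accessible regions of all barcodes (right); colour and printed numbers give the correlation. Fontan replicate 3 has 0.98 and 0.96 with the controls on the left and 0.96 and 0.95 on the right, above its values with the other Fontan libraries (0.87 to 0.89 and 0.88 to 0.91).

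In stellate-like nuclei, the main collagen-producing cells of the injured liver, COL1A1, COL1A2 and COL3A1 had higher means in Fontan but did not pass (edgeR, adjusted p = 0.656 for each, and 0.137, 0.104 and 0.104 over the list alone). COL1A1 (ENSG00000108821, chromosome 17), which encodes a chain of type I collagen, stood at 236 ± 147 CPM in the 4 Fontan libraries and 56.1 ± 22.0 in the 2 controls (log2 1.91 ± 0.76). COL1A2 stood at 367 ± 158 against 97.0 ± 6.06 (1.90 ± 0.63) and COL3A1 at 883 ± 376 against 249.6 ± 19.3 (1.82 ± 0.63), and the last 2 were higher in all 4 Fontan libraries than in either control. DCN, a proteoglycan that binds collagen, differed by 2.85 ± 1.00, with 118 CPM in Fontan replicate 3 against a control mean of 137 ± 50.6. Of 17 measured members of the fibrillar matrix list 16 were higher (median log2 0.90, fry, adjusted p = 0.547). The median was 1.48 over the 13 members tested without Fontan replicate 3. ACTA2, the smooth muscle actin of activated stellate cells, was listed at 0 in 1 library of each group and differed by 0.47 ± 1.29, or −0.11 without control replicate 1.

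Genes of quiescent stellate cells had higher means as well, in 12 of 13 measured members (median log2 1.02, fry, adjusted p = 0.598), with RELN at 1464 ± 704 CPM against 338 ± 180.4 (2.14 ± 0.78) and ECM1, an extracellular matrix protein, differing by 2.67 ± 1.16. ADAMTS12, a matrix protease, differed by 2.48 ± 0.80, within a matrix turnover list of 5 higher and 2 lower members (median log2 0.54, fry, adjusted p = 0.603). For these 3 stellate lists 0 members passed over all genes in edgeR's test or adjusted over the list alone, with 5, 2 and 1 members at an unadjusted p under 0.05. Of 5153 genes tested in stellate-like nuclei 0 passed, 371 had an unadjusted p under 0.05, DESeq2 called 40, and the lowest adjusted p was 0.656; counts came from as few as 25 nuclei and 54563 UMIs in 1 library. Without any low-count filter 45 genes passed. Leaving out Fontan replicate 3 gave 943 calls, among them COL1A1, COL1A2, COL3A1, DCN, RELN, ECM1 and ADAMTS12. The adjusted fry p was then 0.0266 for the fibrillar matrix list (0.00133 to 0.995 over its alternatives), 0.0561 for the quiescent list (0.00946 to 0.995) and 0.3598 for the turnover list (0.3598 to 0.995), whose median was then 2.32. With all libraries, camera with an estimated correlation gave the fibrillar matrix list an adjusted p of 0.811. The levels of the immediate early list in these nuclei were −1.33, −1.78, 2.14 and −1.60 in Fontan replicates 1 to 4 and 2.24 and 0.34 in the controls, so the matrix difference was not separated from handling of the tissue. The turnover list turned to lower in fry without control replicate 3 (adjusted p = 0.834). Control nuclei and those of Fontan replicate 3 lay in cluster n10, and most nuclei of the other Fontan libraries in n20. Hepatocyte transcripts in these nuclei had 6 members higher and 8 lower (fry, adjusted p = 0.686).

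In endothelial-like nuclei, KDR, the main receptor for VEGF (chromosome 4), stood at 672 ± 256 CPM in Fontan and 211 ± 36.8 in controls (log2 1.68 ± 0.47), higher in each Fontan library than in either control. EDN1, which encodes the vasoconstrictor endothelin, differed by 2.87 ± 0.96 and was listed at 0 in 1 control. NOS3, the endothelial nitric oxide synthase, was lower, at 111 ± 123 against 396 ± 26.1 (−1.87 ± 0.75), and KLF2, a transcription factor induced by laminar flow, differed by −1.81 ± 0.55, from 86.7 ± 76.9 in controls that lay far apart. The flow and angiogenesis list therefore held 8 higher and 8 lower members (median log2 0.11, fry upward, adjusted p = 0.598), and its direction was downward in the camera test. LAMA4 and LAMB1, laminin chains of vessel basement membrane, differed by 2.41 ± 0.74 and 1.96 ± 0.85, within a capillary list of 11 higher and 4 lower members (median log2 0.86, fry, adjusted p = 0.547). STAB2 and LYVE1, scavenger and hyaluronan receptors of sinusoidal cells, differed by 1.15 ± 0.48 and 0.75 ± 0.34, within a sinusoidal list of 11 higher and 5 lower members (median log2 0.44, fry, adjusted p = 0.598). In these 3 lists 0 members passed over all genes or over the list alone, with 5, 3 and 1 at an unadjusted p under 0.05. Their adjusted fry p without Fontan replicate 3 was 0.9196 (0.328 to 0.995 over its alternatives), 0.144 (0.144 to 0.995) and 0.292 (0.292 to 0.995).

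Among genes chosen after their values were seen, ZNF248, a zinc finger gene, stood at 106 ± 22.8 CPM against 9.80 ± 1.39 in endothelial-like nuclei (log2 3.42 ± 0.59). PAM, an enzyme that amidates peptides, differed by 1.48 ± 0.31, BCAT1, a branched-chain amino acid transaminase, by −3.18 ± 0.63, and SEMA4C, a semaphorin, by −2.02 ± 0.41. All 4 genes kept the groups apart, with Fontan replicate 3 on the Fontan side (96.7 CPM of ZNF248). Of 11984 genes tested in endothelial-like nuclei 0 passed edgeR's test, 1422 had an unadjusted p under 0.05, DESeq2 called 16, and the lowest adjusted p was 0.411. Without any low-count filter 457 passed, and leaving out Fontan replicate 3 gave 747 calls, 485 higher and 262 lower, among them KDR, NOS3, LAMA4, LAMB1, ZNF248, PAM, BCAT1 and SEMA4C. Non-overlapping groups made up 27.8% of genes, where chance gives 13.3%. Control replicate 1 and Fontan replicate 3 lay mainly in cluster n2, control replicate 3 in n27, and Fontan replicates 1, 2 and 4 in n1, n8 and n3. Control nuclei gave 90639 and 116485 UMIs in this class against at least 660455 in each Fontan library. Hepatocyte transcripts in these nuclei had 8 members higher and 6 lower (fry, adjusted p = 0.783).

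In macrophage-like nuclei, MT-ATP8, a subunit of the ATP synthase encoded in the mitochondrial genome (ENSG00000228253), fell in Fontan, from 331 ± 68.6 CPM in the 2 controls to 45.9 ± 12.9 in the 4 Fontan libraries. Its log2 fold change was −2.79 ± 0.32 (edgeR, adjusted p = 0.0330), and it was lower in all 4 Fontan libraries than in either control. It was the only one of 6758 genes tested to pass edgeR's test in this class, where 707 had an unadjusted p under 0.05 and DESeq2 called 45; it falls outside the rule for named genes and was chosen after its value was seen. All 13 mitochondrially encoded genes were lower (median log2 −2.34), 13 passed adjusted over the list alone, and the list had an adjusted p of 0.195 in fry. The list was also lower in each measured member in the other classes, at a median log2 of −1.10 in hepatocyte-like (adjusted p = 0.686), −1.17 in endothelial-like (0.547) and −1.01 in stellate-like nuclei (0.547). Its direction in hepatocyte-like nuclei turned without control replicate 3 (adjusted p = 0.834, within 0.0131 to 0.995 over its alternatives). In hepatocyte-like, endothelial-like and stellate-like nuclei the level of the mitochondrial list in control replicate 1 (−0.48, 0.11 and −0.03) lay within the range of the Fontan libraries. That of control replicate 3 (1.58, 1.32 and 1.25) lay above it. The median mitochondrial share of nuclei after the filter was 0.665% and 5.01% in the controls and 0.459%, 0.991%, 0.371% and 1.10% in the Fontan libraries. Nuclei had been filtered on this same share, at most 10%. The lower level of MT-ATP8 was therefore not separated from the RNA quality of the libraries. The call for MT-ATP8 was lost without Fontan replicate 1 (adjusted p = 0.299), 2 (0.214) or 4 (0.271), without control replicate 1 (0.124) or 3 (0.111), at 1000 or more UMIs per nucleus (0.0900) and with wider classes (0.165), and held without Fontan replicate 3 (9.63e-05), within a range of 2.27e-08 to 0.299 over its alternatives. Its log2 fold change stayed between −2.54 and −2.99 over left-out libraries and was −3.09 at 1000 or more UMIs, and −1.92 with wider classes.

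Some genes of Kupffer cells, the resident liver macrophages, had higher means in Fontan. VCAM1 (chromosome 1), an adhesion molecule, stood at 1087 ± 649 CPM against 62.4 ± 6.33 (log2 4.12 ± 0.89) and SLC40A1, the iron exporter ferroportin, at 959.8 ± 466 against 174 ± 65.1 (2.44 ± 0.62). CD5L, a secreted macrophage protein, differed by 1.19 ± 0.40 and SPIC, a transcription factor of iron-recycling macrophages, by 1.72 ± 0.58. All 4 genes were higher in each Fontan library than in either control, and Fontan replicate 3 was the lowest of the 4, at 151 CPM of VCAM1. The Kupffer list had 9 members higher and 7 lower (median log2 0.52, fry, adjusted p = 0.547); 0 passed over all genes in edgeR's test, 4 had an unadjusted p under 0.05, and VCAM1 (adjusted p = 0.0140) and SLC40A1 (0.0202) passed adjusted over the list alone. CD36, a fatty acid scavenger receptor, differed by 2.50 ± 0.77, STAT2, an interferon signalling factor, by −0.87 ± 0.28 and GLUL by −1.33 ± 0.42. The scar-associated list with CD36 split into 3 higher and 3 lower members (median log2 −0.03, fry, adjusted p = 0.777), and its median was −0.51 without Fontan replicate 3. The interferon list with STAT2 split into 5 higher and 12 lower members (median log2 −0.14, fry, adjusted p = 0.767). In edgeR 0 of their members passed over all genes or over the list alone, with 1 and 2 at an unadjusted p under 0.05. The directions of both lists in fry turned without control replicate 3, at adjusted p of 0.560 (0.419 to 0.995 over its alternatives) and 0.328 (0.328 to 0.995). Leaving out Fontan replicate 3 gave 784 calls, 373 higher and 411 lower, including these 7 genes, with adjusted fry p of 0.146 for the Kupffer list (0.146 to 0.995 over its alternatives), 0.896 for the scar-associated list (0.419 to 0.995) and 0.530 for the interferon list (0.328 to 0.995), and without a low-count filter 175 genes passed. Control replicate 1 and Fontan replicate 3 lay in cluster n0, control replicate 3 in n15, and the other Fontan libraries in n6. Hepatocyte transcripts had 8 members higher and 6 lower in this class (fry, adjusted p = 0.883).

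**Figure D4:**
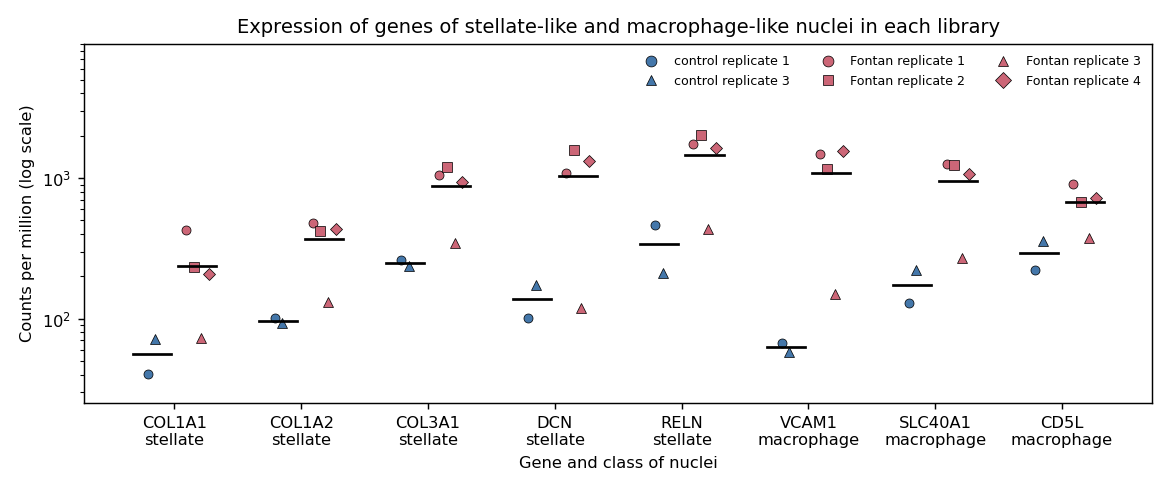
CPM on a log axis (y) of 5 genes in stellate-like nuclei and 3 genes in macrophage-like nuclei (x axis) in the 2 control libraries (blue) and 4 Fontan libraries (red); points are libraries and horizontal bars are group means. Fontan replicate 3 (red triangles) lies below the other Fontan libraries for each gene, as for VCAM1 at 151 CPM against a Fontan mean of 1087 and a control mean of 62.4.

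Of the 54 pairs of a gene list and a class, fry moved 0 past an adjusted p of 0.05, and 3 had an unadjusted p under 0.05. These were the mitochondrial list in macrophage-like nuclei and the glucose and bile acid lists in hepatocyte-like nuclei. The competitive test camera with a preset correlation of 0.01 called 13 pairs, 7 higher in Fontan, and with an estimated correlation it called 0, with 1 at an unadjusted p under 0.05. T/NK-like and cholangiocyte-like nuclei were not tested for genes, since the controls held only 15 and 10 T/NK-like nuclei and 1 control library only 10 cholangiocyte-like nuclei.

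Whether zonation differed between the groups was asked by ranking hepatocyte-like nuclei from periportal to pericentral within each library. The mean score, as the log2 ratio of pericentral to periportal transcripts, was −1.13 ± 0.73 in controls and −0.38 ± 0.78 in Fontan (SD over libraries). Fontan replicate 3 scored −1.50, near control replicate 1 at −1.65. Between the nuclei at the pericentral and periportal ends of this order, 357 of 15230 genes differed over all libraries, 151 higher at the pericentral end and 206 lower. The change of this zone difference with the group was tested in 18348 genes, and 0 passed edgeR's test, with 460 at an unadjusted p under 0.05. Leaving out Fontan replicate 3 gave 1 call.

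Chromatin accessibility was compared per library over all barcodes. Total counts in peaks were 3793876 and 56385080 in the controls, from 1346 and 15275 barcodes, and 6210435, 25177007, 12571265 and 2637888 in the Fontan libraries, from 2482, 4674, 4569 and 1218 barcodes. Across regions, the log2 CPM of Fontan replicate 3 correlated at 0.957 and 0.953 with the controls and at 0.879 to 0.910 with the other Fontan libraries. Of 45427 autosomal regions tested in all barcodes, 0 passed edgeR's test, 2376 had an unadjusted p under 0.05, DESeq2 called 2, and the lowest adjusted p was 0.814. Non-overlapping groups made up 13.4% of regions, where chance gives 13.3%. With Fontan replicate 3 left out, 2801 regions passed, 989 more accessible in Fontan and 1812 less.

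Promoter accessibility over all barcodes was then compared with expression in hepatocyte-like nuclei across 15902 genes, so the readouts cover different sets of nuclei. With accessibility from hepatocyte-like barcodes only, the Pearson r was 0.229 across 15799 genes. Over all barcodes, log2 fold changes of regions within 1000 bases of a gene start and of its RNA correlated with Pearson r = 0.228 and Spearman rho = 0.189 across genes, which are not independent and share the same donors. The sign was shared by 56.9% of all genes and by 67.7% of the 1664 genes with an unadjusted p under 0.05 in expression. No gene passed the expression test, so no share could be given over called genes.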

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

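Of the tests in this part, those of an exchange of libraries, of tissue stress, of unnamed mixed nuclei, of the UMI minimum and of hepatocyte recovery were chosen after the result was seen, as was the draw of equal numbers of nuclei. The exchange and recovery tests were each redefined more than once after their values were seen, and 1 earlier form of each had left its explanation open. The free RNA test was planned over 3 classes and split by class after its values were seen, with its bounds kept.

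In 15 of 125 values measured in the 4 Fontan libraries, 1 library lay far from the other 3, with a gap to the nearest, as a share of the group's whole range, past Dixon's 95% limit for 4 samples. Chance alone does this in about 1 in 20 values, and many of these values come from the same library and are not independent. In 10 values Fontan replicate 3 stood apart towards or past the control side. In hepatocyte-like nuclei these were ORM1 (126, 89.5, 316 and 92.9 CPM in Fontan replicates 1 to 4, gap over range 0.84), LCN2 (0.106, 0.154, 1.18 and 0.202 CPM, 0.91), GLUL (32.8, 32.9, 59.6 and 29.5 CPM, 0.89) and the levels of the glucose list (0.33, 0.42, −0.20 and 0.41, 0.84), the bile acid list (0.66, 0.66, −0.53 and 0.67, 0.99) and the acute phase list (−1.61, −1.42, 1.51 and −1.19, 0.86). In other classes they were NOS3 (49.3, 51.3, 295 and 48.2 CPM, 0.99) and SEMA4C (19.7, 20.7, 26.9 and 20.3 CPM, 0.87) in endothelial-like nuclei and COL1A2 in stellate-like nuclei (479, 419.7, 132 and 437 CPM, 0.83). The 10th was the number of deposited barcodes (6977, 6844, 12360 and 6359, 0.90). Fontan replicate 3 also had the highest share of macrophage-like nuclei (3.59%, 2.68%, 9.59% and 3.20%, 0.87), with Wilson 95% CI 9.003 to 10.2. The other 4 concerned Fontan replicate 2 or 4, namely deposited total UMIs (36367684, 64315913, 33162251 and 38394523, 0.83), snATAC median counts per barcode (1968.5, 4653, 2185 and 1691, 0.83), the periportal list (0.03, 0.41, 0.06 and 0.06, 0.92) and KLF2 in endothelial-like nuclei (23.4, 21.4, 22.2 and 33.9 CPM, 0.84).

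The first pattern weighed is that 1 Fontan library lies with the control libraries in hepatocyte-like nuclei. In nuclei of 1500 to 3000 UMIs its mean correlation with the controls stayed 0.193 above that with the other Fontan libraries (0.349 with 169 nuclei from every library), and after the gene length trend was removed 0.0971, against 0.100 in all nuclei, which argues against depth and gene length as the whole cause. An exchange of 2 libraries between the groups would need a control that resembles the other 3 Fontan libraries. In expression the highest such correlation stayed below the lowest among these 3 in all 4 classes. The smallest gap, −0.0391, was in hepatocyte-like nuclei. In 1 of 8 pairs of a control and a class the control was still closer to these 3 than to the remaining control. Accessibility went the other way. Control replicate 3 correlated at 0.933 with Fontan replicate 2 over all barcodes, above the lowest correlation among these 3 (0.927). In hepatocyte-like barcodes these values were 0.954 and 0.929, so an exchange stays open. Fontan replicate 3 was the highest Fontan library in 7 of 8 pairs of a class with the immediate early or hypoxia list. In these pairs 1 control library was high as well. In hepatocyte-like nuclei it was also the highest Fontan library in the acute phase list (1.51) and the lowest in the bile acid list (−0.53). The 8 pairs repeat the same lists over classes of the same library. The count may therefore restate that the library lies with the controls, and it cannot decide whether stress of the tissue before freezing contributes. A single wrong label stays open, although the shares of endothelial-like, T/NK-like and hepatocyte-like nuclei lay on the side of the Fontan group, and a difference between the livers or an unrecorded batch was not tested.

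The second pattern is that the same library lies with the controls in stellate-like and macrophage-like nuclei. Over genes above their level in hepatocyte-like nuclei, the difference was 0.286 in stellate-like and 0.1054 in macrophage-like nuclei, against 0.4739 and 0.1251 over all genes. Both stayed above the bound, which argues against free hepatocyte RNA as the whole cause. The values over all genes used another count filter and scaling, so the drop does not measure a part for it. Such a part stays open. In endothelial-like nuclei the library was about as close to both groups, with a difference of 0.0038 over all genes. Over genes above their hepatocyte level it was 0.0442, between the bounds set before it was seen. The test therefore could not decide on free hepatocyte RNA in this class.

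The third pattern is the lower share of endothelial-like nuclei in the controls. With unnamed mixed nuclei counted in their class, the lowest Fontan share lay 5.755 percentage points above the highest control share, and with nuclei of 300 or more UMIs 2.031, so neither choice alone accounts for the gap. Against a higher recovery of hepatocyte nuclei in the controls, 3 of the 4 Fontan libraries had a ratio of endothelial-like to macrophage-like nuclei at least 1.953 above the highest control ratio at all 6 settings. For the remaining library the gap was 0.243 with all filters as described and −0.029 with 300 or more UMIs, so this explanation stays open there. Barcodes under 300 UMIs were not examined, and a loss of endothelial nuclei during the handling of control tissue stays open beside a difference between the livers.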

How the results depend on the processing

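Numbers of calls depended on 1 library, on the test and on the low-count filter. Leaving out each library in turn gave between 0 and 4310 genes in hepatocyte-like, 0 and 943 in stellate-like, 0 and 747 in endothelial-like and 0 and 784 in macrophage-like nuclei, 0 and 6 list-class pairs, 0 and 1 zone genes and 0 and 2801 regions, each highest without Fontan replicate 3. Of 70 named genes, 1 passed with all libraries and 57 of the 69 tested without Fontan replicate 3 passed. DESeq2 called 445, 40, 16 and 45 genes in the 4 classes and 2 regions, against 0, 0, 0 and 1 genes and 0 regions with edgeR. Without a low-count filter 45 stellate, 457 endothelial and 175 macrophage genes passed. Macrophage calls were 0 at 1000 or more UMIs and 0 with wider classes, and camera called 13 pairs with a preset correlation and 0 with an estimated one (1 at an unadjusted p under 0.05). The cause of these shifts was not tested.

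The replicate numbers were not taken to pair libraries, since control and Fontan livers came from different people. Deviations of same-numbered libraries from their group mean correlated at −0.356 and −0.514 in hepatocyte-like, −0.104 and −0.238 in stellate-like, −0.0937 and −0.218 in endothelial-like and −0.119 and −0.364 in macrophage-like nuclei and at −0.0564 and −0.232 in regions. The deviations of the controls are mirror images of each other, so these correlations cannot decide whether the numbers pair libraries. With the replicate block 0 genes passed in edgeR in hepatocyte-like, stellate-like and endothelial-like nuclei (171, 61 and 279 at an unadjusted p under 0.05), 4 in macrophage-like nuclei, 0 regions and 0 list-class pairs. The block turned CYP3A4 to −0.50 and HMGCS1 to −0.48 and reversed the cholesterol, hepatocyte transcript (macrophage), fetal tumour, hypoxia and stress-response lists, each at an adjusted p of 0.995.

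None of the other results that reversed was past the threshold. The macrophage share difference was −0.0292 at 300 or more UMIs, −0.334 at a mitochondrial limit of 25% and −0.0380 with wider classes, and −0.376 to 2.40 over left-out libraries. CYP3A4 was −0.0262 with DESeq2, −0.0263 with its size factors and −0.00497 at 1000 or more UMIs. HMGCS1 was −0.0398 with DESeq2, −0.0399 with its size factors and −0.0119 without a filter. ACTA2 was −0.11 at a mitochondrial limit of 25%. Over left-out libraries SQLE ranged from −0.99 to 1.53, CYP3A4 from −0.35 to 0.43, CYP2E1 from −0.48 to 1.18, HMGCS1 from −0.75 to 1.44 and ACTA2 from −0.11 to 0.73. Reversed lists had adjusted p of 0.625 (preset) and 0.811 (estimated camera) for endothelial flow, and 0.995 and 0.995 for fetal tumour genes. The hepatocyte transcript list had 0.739 with wider classes in stellate-like nuclei, 0.994 (preset), 0.995 (estimated) and 0.806 (wider classes) in endothelial-like nuclei, and 0.914 (1000 or more UMIs) and 0.598 (wider classes) in macrophage-like nuclei. Wider classes also reversed the matrix turnover list (0.8995) and the macrophage interferon list (0.742). Over left-out libraries the adjusted p ranged from 0.441 to 0.964 for cholesterol, 0.328 to 0.9196 for endothelial flow, 0.374 to 0.868 for interferon, 0.473 to 0.868 for the mitochondrial list in hepatocyte-like nuclei, 0.328 to 0.912 and 0.490 to 0.963 for hepatocyte transcripts in endothelial-like and macrophage-like nuclei and 0.189 to 0.987 for fetal tumour genes. That range was 0.3598 to 0.912 for matrix turnover, 0.466 to 0.912 for scar-associated macrophages and 0.328 to 0.912 for the macrophage interferon list. At 1000 or more UMIs endothelial-like genes could not be run, and T/NK-like and cholangiocyte-like tests were not run for want of nuclei.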

Other observations

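In hepatocyte-like nuclei, MX1, an interferon-induced antiviral gene, stood at 25.2 ± 8.92 CPM in the 4 Fontan libraries and 107 ± 97.9 in the 2 controls (log2 −2.09 ± 0.59), with the controls far apart. The interferon list had 15 of 19 members lower (median log2 −0.64, fry, adjusted p = 0.598), with 0 members passing in edgeR and 6 at an unadjusted p under 0.05. Without Fontan replicate 3, 5 members passed as lower and 1 as higher, and the adjusted fry p was 0.459. The direction of the list in fry turned without control replicate 3. ATF4, a stress-response transcription factor, differed by −1.32 ± 0.51, within a stress-response list of 11 lower and 6 higher members (median log2 −0.46, fry, adjusted p = 0.731). The median of that list was −0.85 without Fontan replicate 3. BNIP3, a mitophagy receptor, differed by 1.18 ± 0.44, against the direction of its hypoxia list, in which 15 of 21 members were lower (median log2 −0.22, fry, adjusted p = 0.765). In each of these 2 lists 0 members passed in edgeR and 2 had an unadjusted p under 0.05, and without Fontan replicate 3 there passed 7 and 8 as lower and 1 each as higher (fry, adjusted p = 0.221 within 0.144 to 0.995 over its alternatives, and 0.189 within 0.156 to 0.995). Of 3 genes chosen after their values were seen, GLYAT, which conjugates glycine, stood at 461 ± 301 CPM against 18.5 ± 2.30 (4.64 ± 1.15). ESR1, the oestrogen receptor, stood at 1152 ± 532 against 182 ± 28.8 (2.67 ± 0.67) and SLC40A1 at 82.5 ± 18.1 against 23.3 ± 4.93 (1.82 ± 0.39). These 3 kept the groups apart, with 0 passing edgeR's test over all genes.

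Among the 15 splits of the libraries into 2 and 4, too few for a share under 0.05, the real split gave 0 hepatocyte-like, 0 stellate-like, 0 endothelial-like and 1 macrophage-like genes and 0 regions in edgeR. The highest other split gave 3777, 2, 648 and 328 genes and 158 regions. For hepatocyte-like, endothelial-like and macrophage-like genes it set Fontan replicate 3 and control replicate 1 against the rest, which points to a structure of the samples that the groups do not describe. These libraries also had the lowest median depth after the filter, at 2081 and 1221 UMIs per nucleus, and this split was not tested apart from depth.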
